A study of Drosophila melanogaster with 3 samples.

How the data were processed

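Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h that carried a transgene for C15 fused to enhanced green fluorescent protein (C15-eGFP). C15, also known as clawless, is an NK-type homeodomain transcription factor. Per the labels, the fusion protein was recovered with an antibody against GFP, chromatin was sheared in a Bioruptor sonicator, and fragments ranged from 200 to 800 bp. The labels' antibody field names C15 itself, while their description names GFP, and the description was followed. There was 1 group of 3 biological replicates and no second condition. The labels name a control experiment, which was not used here, and no read data were used.

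The deposited files are peak lists in narrowPeak layout on the dm6 assembly, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. Each replicate had 1 ranked list and 1 thresholded list made from its own alignment, and the series had 4 ranked and 4 thresholded lists made from the alignments of all 3 replicates, per the deposited descriptions of the files. One of these series-level lists is called conservative by the authors and was the main list. The other 3 series-level thresholded lists are called list A, list B and list C here, in order of length, because the files do not name the inputs compared in each. The height of each peak is an enrichment signal deposited by the authors, which was used only to rank and describe peaks within a list. A score column deposited by the authors, nominally the −log10 of a q value, dips slightly below 0 in the series-level lists and served only to break ties. The ranked lists also hold the −log10 of the global irreproducible discovery rate (IDR), deposited by the authors, which measures how poorly a peak's rank repeats between the inputs compared. Every thresholded list was found to be a subset of exactly 1 ranked list, with all of its peaks at a −log10 IDR of 2 or more, an IDR of 0.01 or less. In the conservative list, 1272 ranked peaks met that level and 45 of them were absent from the thresholded list, which holds 1227 peaks. The further 32 columns of the series-level ranked lists hold values of each input and were not used, since nothing names the input. The files give no read counts, so the depth of each library is unknown and no interval that needs it is given.

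Peaks were placed on the Ensembl release 115 annotation of the Release 6 assembly, and sequences were taken from the RefSeq copy of the same assembly. The highest peak end lay within the sequence of each of the 7 chromosome arms. A peak was classed by its summit as promoter (within 500 bp of an annotated transcription start, coding or not), 5′ UTR, 3′ UTR, coding exon, other exon, intron, intergenic or, outside the chromosome arms, scaffold. Its gene was the protein-coding gene with the nearest transcription start. A promoter peak can therefore lie far from the start of the gene it is assigned to. Coordinates are 1-based.

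The tests and lists were fixed before the data were examined. Shares of peaks and counts of list genes with a peak were compared with 10000 draws of as many peaks from the matching ranked list, in two-sided permutation tests whose smallest p is 0.0002. Overlap between replicate lists required 1 bp. Motifs were searched on both strands of 200-bp windows centred on the summit, against 5 windows per peak of the same GC content (in steps of 2 percentage points) from ranked peaks that overlapped no thresholded peak, with two-sided Fisher's exact tests. There were 22 gene lists, 20 motifs and all 2080 6-mers with reverse complements merged, each family with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 362 gene list entries, 356 matched a protein-coding gene by symbol. The 6 entries that did not (Dl, h, CG6218, dys, duf and nos) were left out. Scaffold peaks did not enter the motif tests. In the gene list tests they stayed among the peaks counted and drawn but were assigned no gene.

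The genes named are those nearest the 25 conservative peaks of highest signal, the 4 members with the highest-signal peak of each gene list past the test, the 2 such members of each other list, and every member of the NK homeobox cluster. The motifs named are all fixed motifs past the test and the 5 6-mers of lowest p in each direction. Outside this rule, the homeodomain and Tinman words that did not pass are named because C15 is an NK-type homeodomain protein, and the Zelda and Mad words because their direction changed under an alternative. These and other genes, peaks or words outside the rule were chosen after their values were seen.

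On simulated peak sets drawn from the 138473 ranked peaks, the share test called 8 of 100 sets without a difference and 100 of 100 sets in which promoter peaks were drawn 1.5 times as often. The gene list test called the ribosomal protein list, with its peaks drawn 10 times as often, in 10 of 10 sets. It made 0 calls in 210 tests of the other 21 lists there. That list is the largest, and the sensitivity for smaller lists or smaller excesses was not simulated. The 6-mer test called a word planted in 10% of windows in 5 of 5 sets, with 19 calls among 10395 tests of other words, and made 0 calls for other words without planting.

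Alternatives tried were the IDR threshold alone, the other series-level lists, leaving out each replicate (peaks of one remaining replicate list that overlap the other), the overlap that counts as shared, the promoter width, the assignment of genes, draws matched on promoter class, the motif window and the background. An IDR of 0.001, keeping 1 of any peaks that overlap each other, keeping only peaks found in all 3 replicate lists, and a 400-bp window for 6-mers were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.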

Results

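Sites recovered with C15-eGFP in whole embryos were described from the authors' peak lists of 3 biological replicates and from the conservative list that the authors made from all of them. The design has no second condition, so the comparisons are between replicates, and between peaks past the authors' threshold and the ranked peaks from which they were taken. Replicates 1, 2 and 3 had 1080, 775 and 557 thresholded peaks, a mean of 804 ± 263 (SD, n = 3), out of 76494, 100507 and 72927 ranked peaks. The conservative list held 1227 peaks out of 138473 ranked peaks, and these lay nearest to 1027 different protein-coding genes. The median conservative peak was 316 bp wide, the same as in lists A, B and C, so this width is not read as a property of the sites. The median signal of conservative peaks, an enrichment value from the authors' peak caller, was 130.1. All coordinates are on dm6.

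The first question was how far the replicates recovered the same sites. Of the 557 peaks of replicate 3, 457 (82.0%) overlapped a peak of replicate 1, and of the 775 peaks of replicate 2, 536 (69.2%) did. The lowest share was that of replicate 1 in replicate 3, at 454 of 1080 peaks (42.0%). Over the 6 ordered pairs the mean was 61.4%, while between 0.554% and 1.43% of the ranked peaks of the same replicates overlapped the other thresholded list. In two-sided permutation tests all 6 pairs reached p = 0.0002, the smallest that 10000 draws can give, and the adjusted p was also 0.0002. Most ranked peaks fell short of the threshold, so these draws do not separate shared binding of C15-eGFP from any other strong signal that replicates share. Of the conservative peaks, 367 (29.9%) overlapped a thresholded peak in all 3 replicates and 270 (22.0%) in none. The median signal was 237.5 in the former and 89.1 in the latter. Replicates differed in the share of peaks on unplaced scaffolds, which was 7.50% in replicate 1, 0.129% in replicate 2 and 3.41% in replicate 3, against 0.489% of the conservative list.

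The tagged gene was examined first and apart from other loci. The sources used here do not state which genomic sequence the transgene holds, and its copy number was not tested. C15 (FBgn0004863) lies on the plus strand of 3R from 21499986 to 21512814, inside the NK homeobox cluster. No conservative peak had C15 as its nearest gene. One conservative peak lay within 20 kb, at 3R 21520268 to 21520449, in intergenic sequence 7542 bp past the annotated end of C15 and 572 bp from the transcription start of sp3. Its signal was 411.1, and each replicate list held a peak with its summit within 10 bp of it. Its distance of 7542 bp kept it in the count at 10, 20 and 50 kb.

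The neighbouring NK genes showed few peaks. A promoter peak with a signal of 131.4 lay 289 bp from the start of tin (FBgn0004110), the tinman gene required for heart formation, at 3R 21378530 to 21378845, and only replicate 2 had an overlapping peak. None of bap (FBgn0004862), lbl (FBgn0008651), lbe (FBgn0011278) and slou (FBgn0002941), the homeobox genes of visceral and somatic muscle and heart patterning, was the nearest gene of a conservative peak. A conservative peak at 3R 21420071 to 21420386, signal 103.3, lay inside an intron in the lbl gene span although its nearest start was that of CheB93b, and no replicate list held it. It was chosen after its values were seen. In all, 1 of the 6 cluster genes had a peak, against 1.17 in the draws (permutation test, adjusted p = 1).

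**Figure D1:**
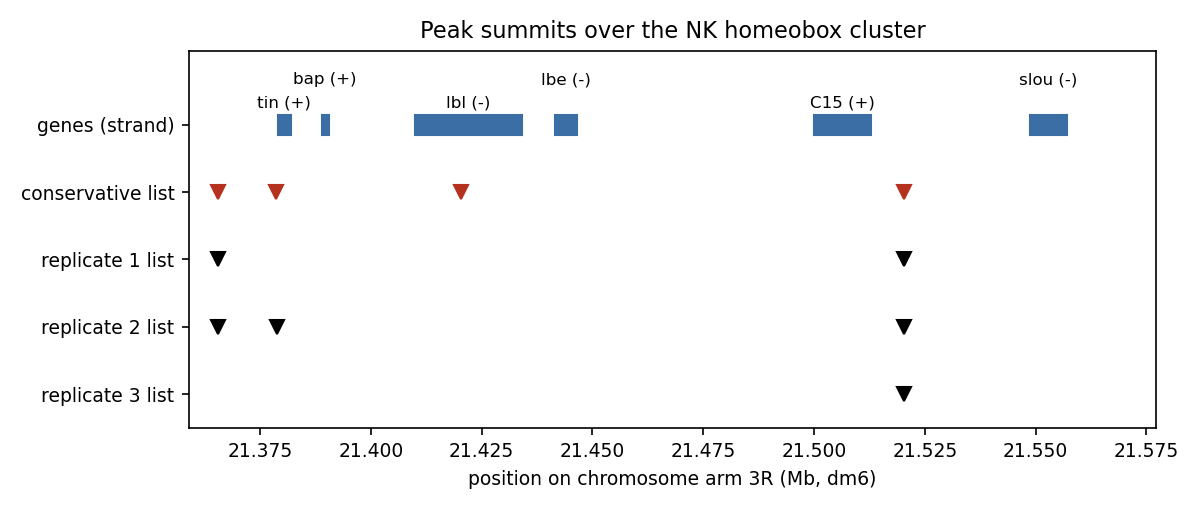
Map of the NK homeobox cluster on 3R (horizontal axis, Mb on dm6) with its 6 genes as bars and peak summits as triangles, 1 row per peak list. The summit past the end of C15 appears in the conservative list and in all 3 replicate lists, and that near tin in the conservative and replicate 2 lists.

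The next question was where in the genome the sites lie. More than any other class, conservative peaks lay at promoters, with 674 of 1227 summits (54.9%) within 500 bp of a transcription start, against 15.2% of ranked peaks. The replicate lists gave 57.6% ± 4.99 (SD, n = 3). Introns held 404 peaks (32.9%, against 40.0% of ranked peaks) and intergenic sequence 119 (9.70%, against 22.8%). Coding exons held 5 peaks (0.407%, against 14.3%) and 3′ UTRs 9 (0.733%, against 4.85%). The shares of these 5 classes differed from the ranked list at an adjusted p of 0.00032 in two-sided permutation tests, each with an unadjusted p of 0.0002, the smallest that the draws can give. The classes divide up the same peaks, so a higher promoter share by itself lowers the shares of the others. Shares among peaks outside promoters were not tested, and the lower intron share does not show that introns were avoided. In proportion, the intron share fell less than that of every other class outside promoters. Among peaks outside promoters, introns therefore made up a larger part of conservative than of ranked peaks. The share in 5′ UTRs (4 peaks, 0.326% against 0.969%) differed at an adjusted permutation p of 0.0235, and those of other exons (adjusted p = 0.165) and scaffolds (adjusted p = 0.0528) did not pass the threshold. The 5′ UTR call rests on 4 peaks and was lost in list A, without any 1 replicate, at an IDR of 0.001 and among peaks in all 3 replicate lists, with adjusted permutation p values from 0.0023 to 0.785 over the alternatives. No replicate list passed for 5′ UTRs. The scaffold share depended on the list. It was higher than in ranked peaks in list B (5.22% against 1.78%, adjusted permutation p = 0.00027), replicate 1 (7.50% against 1.69%, adjusted permutation p = 0.00027), replicate 3 (3.41% against 1.37%, adjusted permutation p = 0.0008) and without replicate 2 (3.74% against 1.69%, adjusted permutation p = 0.0048). Without replicate 3 it was lower (0.189% against 1.69%, adjusted permutation p = 0.0024), as it was among peaks in all 3 replicate lists (0 peaks, adjusted permutation p = 0.0491), and over the alternatives the adjusted p ranged from 0.00027 to 0.852. The direction of the promoter share and its call held in all 12 alternatives, from 43.4% with a promoter width of 250 bp to 65.8% with 1000 bp.

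**Figure D2:**
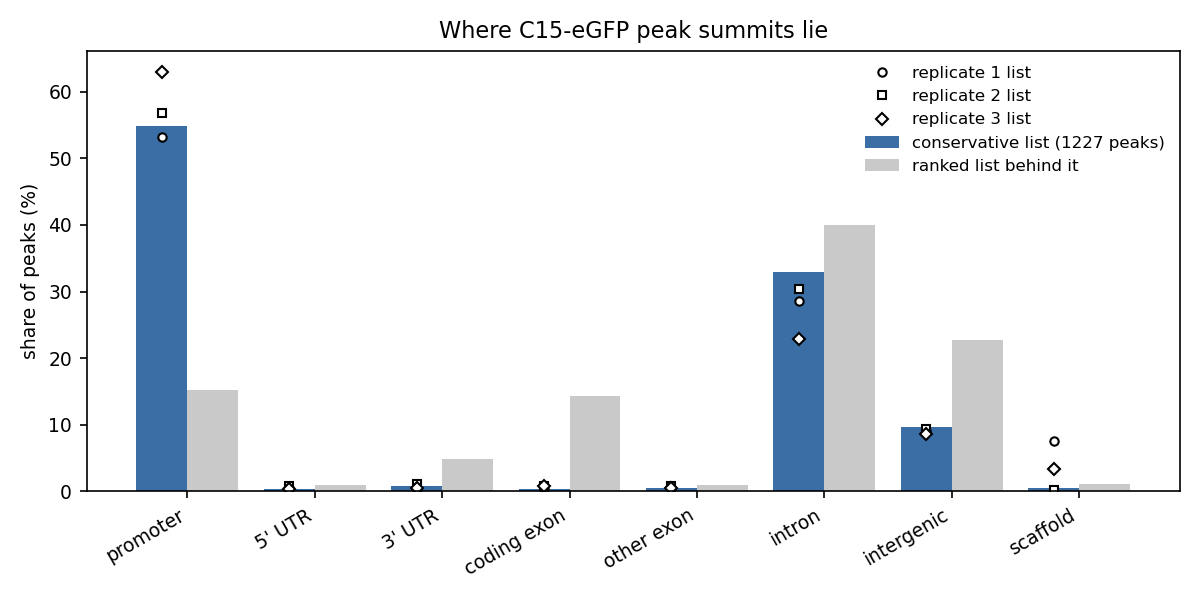
Share of peaks (%) in each annotation class for the conservative list (blue bars) and for the ranked list behind it (grey bars), with the 3 replicate lists as points. Promoters hold 54.9% of conservative and 15.2% of ranked peaks, and replicate 1 has the highest scaffold share, 7.50%.

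The share of peaks on each chromosome arm was compared with that of the ranked peaks. The X chromosome held 231 conservative peaks (18.8%, against 18.5% of ranked peaks), 3L 273 (22.2%), 3R 267 (21.8%), 2L 234 (19.1%) and 2R 212 (17.3%). Chromosome 4 held 4 peaks and the Y chromosome 0. In the conservative list no arm passed the two-sided permutation test, with an adjusted p of 0.764 for X and a lowest adjusted p of 0.232, for chromosome 4. The replicate lists had 17.0% ± 0.886 (SD, n = 3) of their peaks on X. Without replicate 3, X held 18.9% of the peaks shared by replicates 1 and 2 and differed from replicate 1's ranked list at an adjusted permutation p of 0.0364, while the adjusted p over the 10 alternatives ranged from 0.0364 to 1. In the replicate 1 list itself, X held 17.6% of peaks against 14.5% of ranked peaks (adjusted permutation p = 0.0140). Peaks on 3R were fewer than among ranked peaks in list B (19.9% against 24.4%, adjusted permutation p = 0.0014), in replicate 1 (18.6% against 25.03%, adjusted permutation p = 0.0014) and in replicate 3 (20.6% against 25.4%, adjusted permutation p = 0.0448), and the adjusted p for 3R ranged from 0.0014 to 1 over the alternatives. The Y chromosome held 0 peaks of list A against 0.523% of ranked peaks (adjusted permutation p = 0.0014), with the same range.

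The 25 conservative peaks of highest signal, from 1476.7 down to 558.7, all overlapped a peak in each of the 3 replicate lists, and 18 of them lay at promoters, 5 in introns and 2 in intergenic sequence. The highest, at 2L 6612536 to 6612883, lay in an intron 1032 bp from the start of CG11050 (FBgn0031836), a gene without a named function in the annotation. The next lay at the promoters of Ugalt (FBgn0024994), a UDP-galactose transporter gene (X 2703757 to 2704015, signal 1220.4, 45 bp from the start), CG14100 (3L 19590492 to 19590754, signal 1162.4), mRpL41, which encodes a mitochondrial ribosomal protein (2R 15217625 to 15217871, signal 1102.8), Tcs5 (3L 5139386 to 5139619, signal 875.4) and CG7601 (3R 29736733 to 29736956, signal 823.7). The remaining promoters included those of 2 further mitochondrial ribosomal protein genes, mRpS10 (signal 721.0) and mRpL23 (587.3). They also included ph-p, a Polycomb group gene (737.5), Chro, which encodes the chromodomain protein Chromator (698.8), PNPase (671.5), CenG1A (725.5), px (671.1), CG5611 (656.6), Elp5, an Elongator subunit gene (619.3), Fkbp14 (602.0), CG13390 (594.7), eIF6 (571.6) and CG1635 (558.7). Intronic peaks lay nearest to CG32772 (656.5), the transcription factor gene Adf1 (653.0), CG42507 (604.4) and the HMG-box gene HmgZ (578.8), and the intergenic ones to CG13323 (669.5) and tara (560.1).

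Gene lists fixed in advance asked which classes of genes had a peak more or less often than the ranked peaks would give. The draws give more weight to genes with many ranked peaks nearest to them, so an expected count is not a share of genes. Over all genes, 1027 of 13968 protein-coding genes had a conservative peak. Ribosomal protein genes exceeded the draws most in number, with 16 of 44 genes (36.4%) against 2.02 in the draws, a 7.92-fold excess (two-sided permutation test, adjusted p = 0.0022). All 16 had their highest-signal peak at the promoter. The highest signals were at RpL7 (2L 10200998 to 10201098, signal 283.2, 24 bp from the start), RpL32 (3R 30046189 to 30046270, 265.5, 53 bp), RpS27 (3R 25247445 to 25247536, 249.5, 2 bp) and RpL14 (3L 8600828 to 8601143, 234.3, 20 bp), each with a peak in all 3 replicate lists. No other gene of the 16 had its highest-signal peak in all 3, and those of RpL8, RpL23 and RpLP0 were in none. The replicate lists hit 11.0 ± 3.61 of the 44 genes (SD, n = 3). Of the 16 housekeeping and heat shock genes, 7 had a peak against 0.643 in the draws, a 10.9-fold excess (permutation test, adjusted p = 0.0022). These were led by Gapdh2, a glycolytic enzyme gene (X 15867893 to 15868055, signal 421.2), Hsp27, a small heat shock protein gene (3L 9383831 to 9383980, 318.7), Act5C, a cytoplasmic actin gene (X 5900030 to 5900345, 212.9, 673 bp from its start and 199 bp from another annotated start), and Hsp83 (3L 3192972 to 3193287, 155.2). The replicate lists hit 5.33 ± 1.53 of them (SD, n = 3). The unadjusted p of both lists was 0.0002, the smallest that the permutation draws can give. Each of these calls held in 13 of 14 alternatives: that of ribosomal protein genes ended among peaks found in all 3 replicate lists (6.11-fold, adjusted permutation p = 0.0616), and that of housekeeping genes without replicate 1 (9.88-fold, adjusted permutation p = 0.0594). The counts were smaller in the shorter lists made without 1 replicate. Ribosomal protein genes fell to 8, 6 and 5 without replicates 1, 2 and 3 (9.30-, 7.41- and 5.38-fold), and housekeeping genes to 3, 3 and 4 (9.88-, 16.1- and 17.9-fold).

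A fixed list of 33 other homeobox genes had fewer genes with a peak than the ranked list gives. It shares members such as repo, cad and ems with other lists. It leaves out the Hox and NK lists and several homeobox genes placed only in tissue lists. Some of the latter had a peak (Dll, hth, vvl, pdm2 and zfh1) and others none (such as al, Lim1, B-H1, B-H2, ap, exd, zen, tup, nub and pros). These left-out genes were not tested as a group. Of the 33 genes, 1 had a peak, against 7.28 in the draws (permutation test, adjusted p = 0.0264). This expected count weights genes by their ranked peaks, and no test that gives each gene the same weight was run. It was ems, a head gap gene, with an intergenic peak 13962 bp from its start (3R 13915657 to 13915972, signal 100.1) that no replicate list held. The call held in 4 of 14 alternatives, with an adjusted p between 0.0191 and 0.815. The count stayed below the draws in all 14, at 0.137 times the expected number in the main list and from 0 to 0.372 times elsewhere (0.160 with draws matched on promoter class, adjusted permutation p = 0.0858), and the replicate lists hit 0, 2 and 0 of these genes.

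The other 19 lists did not pass the test. Polycomb and Trithorax group genes had a peak at 6 of 20 genes, against 2.31 in the draws (adjusted permutation p = 0.163). Besides ph-p, with 3 peaks, these included Psc, another Polycomb group gene, whose highest-signal peak (2R 12985113 to 12985296, 394.8) lay 4190 bp from its start and 183 bp from another annotated start. In 5 of 14 alternatives the list passed the test, with an excess of up to 6.72-fold. The EGFR pathway had 7 of 14 genes with a peak, against 3.29 (adjusted permutation p = 0.163), among them spi, which encodes the ligand Spitz, with a promoter peak of signal 224.8 in all 3 replicate lists, and aop, which encodes a repressor of the pathway, with an intronic peak of signal 182.6. With gene bodies extended by 2 kb the EGFR list passed, with 8 of 14 genes against 3.25 (adjusted permutation p = 0.0407), and over the 14 alternatives the adjusted p ranged from 0.0407 to 0.871. Of 19 Dpp/BMP pathway genes 5 had a peak, against 4.13, including intronic peaks at shn (155.8) and bi (134.2). The Wingless pathway had 2 of 18, sgg (183.0, promoter) and nkd (103.2, intron), and the Notch pathway 2 of 16, neur (145.3, intron) and E(spl)malpha-BFM (96.4, intergenic).

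No tissue list passed the test in the conservative list. Distal leg and antenna patterning, a process that involves C15 itself, had 2 of 15 genes with a peak against 5.30 (adjusted permutation p = 0.300). In list A the same count stood against 7.14 and passed the test as fewer (adjusted permutation p = 0.0411), and the adjusted p over the 14 alternatives ranged from 0.0411 to 1. These expected counts weight genes by their ranked peaks, while over all genes 1027 of 13968 had a conservative peak. The 2 genes in the conservative list were Dll, with a promoter peak of signal 374.6 (2R 24814644 to 24814780) in 2 replicate lists, and hth, with an intronic peak of signal 108.1 in none. Amnioserosa and dorsal ectoderm had 1 of 15, ush (112.1, intron), against 2.70, and ush was also the only one of 10 hemocyte markers. Somatic muscle and mesoderm had 4 of 19 against 3.73, led by org-1 (290.5, promoter, 3 replicate lists) and zfh1 (188.8, intron), and heart 3 of 11 against 2.70, led by zfh1 and tin. Gut genes with a peak were bowl (180.3) and fkh (111.3), both at the promoter, 2 of 11. Glia markers had 3 of 9, led by moody (342.7, promoter, 3 replicate lists) and pnt (98.2, intron), and tracheal genes 2 of 12, vvl (108.8, intergenic) and pnt. Neural progenitor genes had 2 of 18, brat (239.5, intron) and pdm2 (74.7, intergenic), gap and pair-rule genes 2 of 20, slp2 (128.0, intergenic) and ems, and Hox genes 1 of 8, Antp (116.4, intron). Germ cell markers had 0 of 9 and epidermis and cuticle genes 0 of 13, against 0.826 and 2.54 in the draws.

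**Figure D3:**
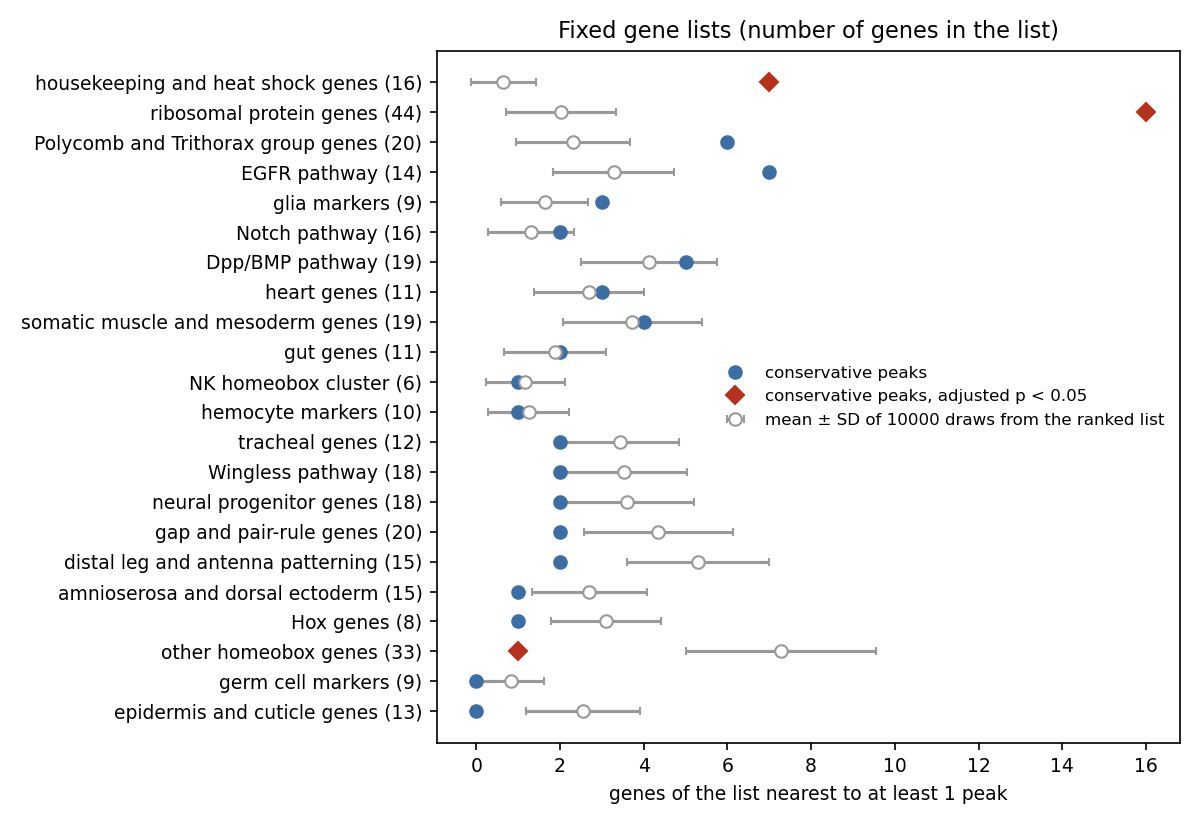
Number of genes of each fixed list nearest to at least 1 conservative peak (filled symbols, red diamonds past the test) beside the mean ± SD of 10000 draws of as many ranked peaks (open circles). Ribosomal protein genes reach 16 against 2.02, housekeeping and heat shock genes 7 against 0.643, and other homeobox genes 1 against 7.28.

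Sequence at the summits was compared with GC-matched windows of ranked peaks past no threshold, at a mean GC content of 35.2% in both. In these windows the homeodomain words, named here although most did not pass because C15 is a homeodomain protein, did not exceed the background. The NK-type word TAATTG occurred in 21.2% of 1221 peak windows and 22.8% of background windows (Fisher's exact test, adjusted p = 0.376), TAATTA in 17.5% and 19.2% (adjusted exact p = 0.290), the core TAAT in 93.4% and 92.1% (adjusted exact p = 0.224), and TTAATGG in 2.87% and 4.59%, which was lower (odds ratio 0.621, adjusted exact p = 0.0222). TAATTG passed as lower in list A (odds ratio 0.820), list B (0.784) and 400-bp windows (0.853), and as higher without GC matching (1.27), where TAAT also passed as higher (3.77). The longer word TTAATTG had an odds ratio of 0.846 (adjusted exact p = 0.232) and passed in 2 of 14 alternatives. The Tinman word TYAAGTG occurred in 8.27% and 7.83% (adjusted exact p = 0.707).

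Words of promoter-binding factors were more frequent in peaks. The background was matched on GC content and not on promoter class, and promoters held 54.9% of conservative and 15.2% of ranked peaks. The main tests therefore do not separate these words from promoter location, and fewer fixed motifs passed with matching within promoter class. GAGAGA, bound by GAGA factor, occurred in 12.2% of windows against 6.06% (odds ratio 2.16, Fisher's exact test, adjusted p = 2.19e-11), and in 11.3% ± 2.27 (SD, n = 3) of the replicate lists' windows. The DNA replication-related element TATCGATA occurred in 2.78% against 0.950% (odds ratio 3.00, adjusted exact p = 1.94e-05) and the M1BP word GGTCACAC in 1.47% against 0.278% (odds ratio 5.35, adjusted exact p = 1.94e-05). Lower in peaks were the Pho word GCCATT (8.52% against 12.8%, odds ratio 0.634, adjusted exact p = 7.32e-05), the Hox-Exd word TGATNNAT (13.4% against 17.0%, odds ratio 0.762, adjusted exact p = 0.00906), the Ets word MGGAAR (29.2% against 32.7%), the CA repeat CACACA (12.2% against 14.8%) and the Su(H) word TGGGAA (9.42% against 11.7%), the last 3 at an adjusted exact p of 0.0447. The count of 9 fixed motifs past the test moved between 0 and 14 over the alternatives. GAGAGA passed in 11 of 14 alternatives, TATCGATA in 10, GCCATT in 9, GGTCACAC in 8 and TTAATGG in 7, with the same direction throughout. Without replicate 3 the odds ratio of GGTCACAC was 2.66 and that of TATCGATA 1.86, neither past the test (adjusted exact p = 0.248 for each), and over all alternatives they ranged from 2.00 to 6.56 and from 1.86 to 8.62. The others passed less often: TGATNNAT passed lower in 4, MGGAAR in 3, CACACA and TGGGAA in 2 each.

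Over all 2080 6-mers, 151 were more and 115 less frequent in peaks, 266 past the test. The lowest p values belonged to ACAGTG, found in 22.1% of peak windows against 6.91% (odds ratio 3.82, Fisher's exact test, adjusted p = 4.85e-47). ACACTG (18.7% against 7.17%), CAGTGG (17.0% against 6.63%), ACTGTG (15.3% against 6.49%) and CTGTGC (15.6% against 7.14%) followed, with adjusted exact p values from 1.95e-28 to 9.47e-17. Each of these shares a run of letters with ACAGTG or its complement, so they overlap it and are not independent findings. The replicate lists had ACAGTG in 24.2% ± 0.670 of windows and CAGTGG in 18.4% ± 1.27 (SD, n = 3). ACAGTG, ACACTG and CTGTGC passed in all 14 alternatives, and CAGTGG and ACTGTG in 13 each (highest adjusted exact p = 0.103 and 0.149). The odds ratio of ACAGTG ranged from 2.09 to 4.64 over the alternatives. The words most reduced in p were GCCAAA (12.6% against 19.3%), GGCAAA (10.9% against 17.1%), CCAAAA (19.7% against 26.7%), AAAGCC (6.72% against 11.5%) and AATGGA (10.5% against 16.1%), with odds ratios from 0.556 to 0.676. These 5 passed in 8 to 12 of the 14 alternatives. The count of 6-mers past the test, 266, fell to 18 with 100-bp windows and rose to 1286 without GC matching.

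Position along the peak, examined after these values were seen, separated the strands of the leading word. On the plus strand ACAGTG occurred 107 times in the bin from 100 to 50 bp before the summits of 1221 peaks and 17 times in the bin from 50 to 100 bp after them, while its complement CACTGT occurred 24 and 103 times. Homeodomain words rose towards the summit together with other AT-rich words. TAATTA occurred 144 times within 50 bp of the summits and 125 times from 200 to 300 bp away, 2.30 times as often per bp, and 20 of the 36 6-mers without G or C rose as much or more (median 2.31). TAATTG rose 1.59 times, and 132 of the 192 6-mers with 1 G or C rose as much or more (median 1.81). GC content was 32.2% in the 50 bp before the summit and 43.8% in the bin from 300 to 250 bp before it.

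**Figure D4:**
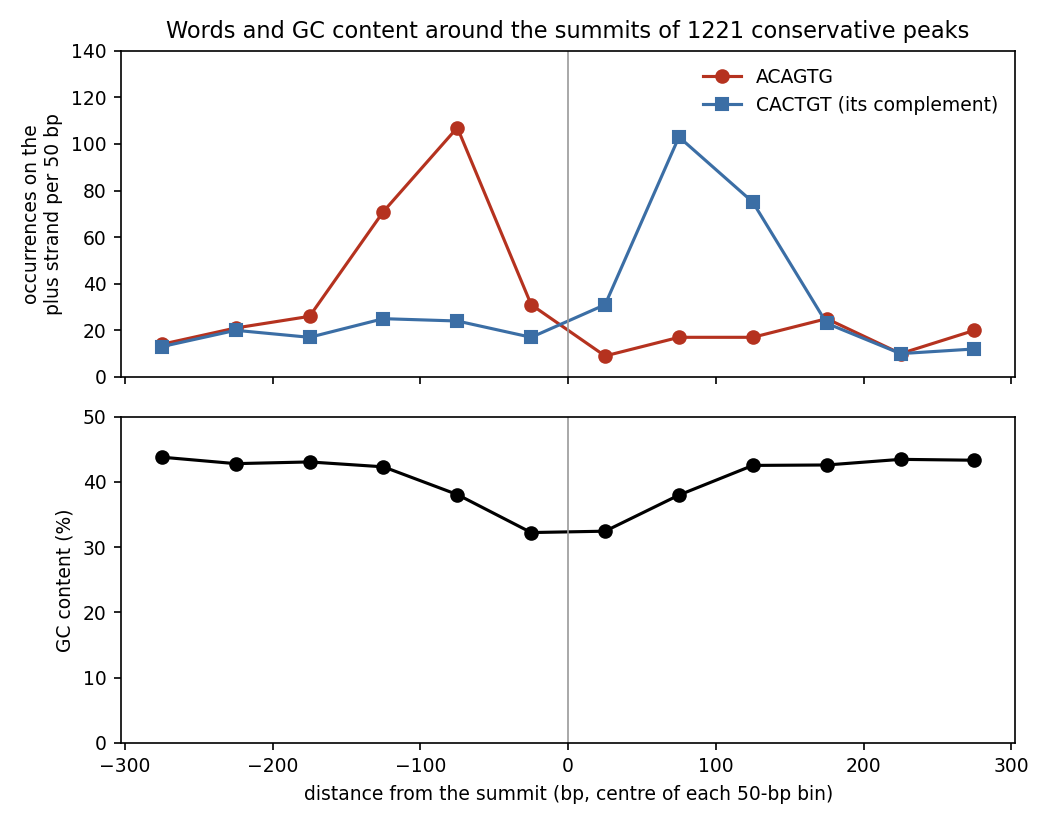
Occurrences of ACAGTG and of its complement CACTGT on the plus strand per 50-bp bin (top) and GC content in % (bottom) against the distance from the summit in bp, over 1221 conservative peaks. ACAGTG peaks at 107 occurrences before the summit and CACTGT at 103 after it, and GC content falls to 32.2% next to the summit.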

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

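The promoter share and the overlap between replicate lists kept their direction and their call in all 12 and all 7 alternatives, and the X share stayed short of the threshold in 9 of 10. Counts past a test moved with the number of peaks, with the background and with the motif window, and the cause was not tested beyond that. Leaving out 1 replicate gave promoter shares from 61.2% to 64.8%, X shares from 15.9% to 18.9%, a replicate overlap from 59.1% to 63.0%, a mean replicate peak count from 666 to 927.5, 1 to 3 gene lists, 0 to 2 fixed motifs and 43 to 83 6-mers, with 1 peak at the C15 locus throughout. These sets hold only 409 to 529 peaks. List A held 2265 peaks with 404 6-mers past the test. List B had 2 peaks within 20 kb of C15, and list C gave 5 fixed motifs. At an IDR of 0.001 or less, added after seeing the data, 551 peaks, 4 fixed motifs and 78 6-mers remained. Among peaks found in all 3 replicate lists, also added then, there were 367 peaks, 1 gene list, 0 fixed motifs and 54 6-mers. Windows of 100 bp gave 2 fixed motifs and 18 6-mers, windows of 400 bp 14 fixed motifs, no GC matching 1286 6-mers, and matching within promoter class 4 fixed motifs.

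Some motif odds ratios changed direction with the test passed before or after the change, and the cause was not tested. Changes of direction in which neither value passed are left out, such as that of TAAT from 1.22 to 0.937 among peaks in all 3 replicate lists. The Su(H) word rose to 1.03 at an IDR of 0.001 and to 1.15 with 100-bp windows, and the Ets word to 1.00 there, none past the test. With 400-bp windows the Zelda word CAGGTA reached 1.38 and CACACA 1.17, both past the test. Without GC matching TAATTA reached 1.53 and TAATTG 1.27, and the Mad word GRCGNC 0.437, all past the test, and the Hox-Exd word 1.12, not past it. Apart from these 9 changes, single genes, lists, motifs and words gave 1094 unchanged calls or counts, 100 calls lost, 17 gained and 138 counts of peaks per gene moved by over 1.5 times. The unknown depth of the libraries limits what the absence of a peak shows. No paired analysis was possible because there is a single group.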

Other observations

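The draws matched on promoter class, the 100-bp windows and the background without GC matching had been planned, and every other test here, like the ranking of words against each other, was chosen after the peaks and words of the report had been seen. At promoters, the position of the summit was asymmetric. Of 674 conservative promoter peaks, 553 (82.0%) had the summit upstream of the nearest transcription start, against 47.0% of 21036 ranked promoter peaks (permutation p = 0.0002, the smallest that 10000 draws can give), and the replicate lists gave 83.1% ± 3.14 (SD, n = 3). The median offset of the summit from the start was -117 bp (quartiles -196.75 and -51 bp, negative upstream), while that of ranked peaks was 25 bp. Promoters with starts on opposite strands within 500 bp of the summit made up 257 (38.1%) of these peaks, against 12.5% of ranked promoter peaks (permutation p = 0.0002) and 37.3% ± 4.03 of the replicate lists' promoter peaks (SD, n = 3).

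Although mRpL41, mRpS10 and mRpL23 stood among the highest peaks, mitochondrial ribosomal protein genes as a group had 3 of 73 members with a peak, against 2.11 in the draws (permutation test, adjusted p = 0.942). Translation initiation factor genes had 4 of 44 against 2.63, proteasome subunit genes 2 of 48 against 1.89 and NADH dehydrogenase subunit genes 1 of 40 against 2.09, none past the test (adjusted permutation p from 0.942 to 1). These 4 groups were taken from gene symbols.

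The leading word of the report was oriented by the side of the summit on which it stood. Within 150 bp, ACAGTG occurred 208 times before and 43 times after the summit on the plus strand, and its complement 65 and 208 times (odds ratio 15.3, 95% interval 9.91 to 24.8 with whole peaks resampled), and no p is given because the split had been seen in the same peaks. At 1147 sites of the other thresholded lists whose windows meet no conservative peak's window, the odds ratio was lower, 3.66 (interval 2.30 to 6.07, permutation p = 0.0002 with the sides of whole peaks swapped, the smallest that the draws can give). The replicate lists, which share peaks with the conservative list, gave 12.7 ± 1.83 (SD, n = 3), and GC-matched windows of peaks past no threshold 1.11 (interval 0.838 to 1.48). Of the 384 peaks with the word or its complement, 273 held it on 1 side only and 111 on both sides (9.09% of 1221 peaks, against 4.10% if the sides were independent). In 101 of these 111, among them peaks at CenG1A, tara and ph-p, ACAGTG lay before and CACTGT after the summit, and in 3, among them that at px, the reverse, while at the other sites it was 33 and 3 of 44. Among 6105 GC-matched windows of peaks past no threshold, 25 held the word on both sides. Of these 25, 14 had ACAGTG before and CACTGT after and 1 the reverse, so the few such windows leaned the same way. In flank windows of 100 bp that begin 25 bp from the summit on each side, matched on their own GC content, it occurred in 16.3% of windows against 3.45% (odds ratio 5.47).

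Strand asymmetry of promoters as the source of that arrangement would leave no orientation elsewhere, yet the odds ratio was 22.0 in the 547 peaks outside promoters (interval 12.8 to 45.9). Without the 32 peaks that hold an annotated transposable element or a 12-bp inverted repeat it was 14.7 (interval 9.71 to 23.6), which argues against those peaks as its source. Annotated transposable elements were met in 2 peaks, and other kinds of repeat were not checked. A 12-bp inverted repeat was present in 2.54% of peaks and in 0.852% of GC-matched windows of peaks past no threshold. Base composition was weighed with other words: of 576 other 6-mers with 3 G or C that share no 4 letters in a row with ACAGTG, 0 were oriented as strongly, and the highest reached 8.83. A candidate explanation is a protein that binds the word beside an AT-rich stretch, on 1 side or both, and whether that is C15-eGFP or another protein recovered by the antibody stays open, since the control was not used here and no biological explanation was tested.

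The lack of an excess of homeodomain words over GC-matched windows could come from the matching itself. Without matching, however, all 36 6-mers without G or C had an odds ratio as high as that of TAATTA (1.53) or higher, with a median of 2.51. TAATTA thus ranked lowest, where a preference strong enough to exceed the rise of AT-rich words would put it near the top. A dilution of sites in 200-bp windows would lift it above such words in 100-bp windows, where it rose to 1.82 but the median also rose, to 2.70, and 35 of the 36 were as high or higher. TAATTG rose from 1.27 to 1.44 and ranked low too, with 178 of 192 6-mers of 1 G or C as high or higher in 200-bp and 174 in 100-bp windows. These rankings cannot exclude a weaker preference, or one in only some of the peaks. Binding to TAAT-type words that are no more frequent than in GC-matched windows, or through other words, may remain, and neither was tested.

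Ribosomal protein genes kept a 5.03-fold excess with draws matched on promoter class (16 genes against 3.18), so promoter location alone would not give it, and housekeeping and heat shock genes kept 6.15-fold. Unspecific recovery of highly transcribed promoters cannot be told apart from binding of C15-eGFP. The 24 promoter peaks nearest to genes of these lists had a median signal of 142.9 and the 650 other promoter peaks 140.3 (permutation p = 0.864). The control experiment was not used here, and whether it would decide the question is not known.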
